A study of Mus musculus with 4 samples.

How the data were processed

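RNA from mouse thymic endothelial cells was measured on 4 Affymetrix mouse expression arrays. Per the labels, 3 arrays held freshly sorted endothelial cells from untreated female C57BL/6J mice aged 6 to 8 weeks, each from several pooled mice. The fourth held expanded endothelial cells, called exEC, which had been sorted, exposed for 48 h to a lentivirus carrying the adenoviral gene E4ORF1 and propagated in culture. The culture medium contained VEGF at 50 ng/ml, FGF-2 at 100 ng/ml, an endothelial growth supplement, heparin and SB431542, an inhibitor of TGF-beta type I receptor kinases, and was renewed every 48 h. Per the labels' protocols, hematopoietic cells were depleted with magnetic beads against CD45, endothelial cells were sorted as CD45-negative, EpCAM-negative and VE-cadherin-positive cells, and 500 ng of total RNA was amplified from its 3′ end and labelled with biotin. The description of the fresh samples instead names stromal cells without CD45, and the labels do not resolve this. The sort used before the lentivirus is described for CD45 and VE-cadherin only. The design text speaks of triplicates for both conditions, and 1 exEC array was analysed here.

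The deposited values are log2 expression values made with GCRMA, a background correction that uses probe sequence followed by normalization between arrays, per the submitters' processing notes. The version, and the set of arrays that were normalized together, are not given in the sources used here. The deposited table held 22690 probe sets with log2 values between 2.20 and 15.74. The values pile up at the lower end, where 20.8% to 22.7% of probe sets on each array had exactly the lowest value of the table, and such values have no order. The median per array lay between 3.85 and 3.93. Arrays have no read depth, so the number of arrays limits the precision. The median SD of the 3 fresh arrays over the genes kept was 0.11 log2 units, with a 90th percentile of 0.31, and 95% intervals of a difference reached a median of 0.36 to either side.

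Probe sets were named through GEO's platform annotation. Of the probe sets, 20380 had 1 gene symbol, 691 had several, 1555 had none and 64 were control probe sets, and only those with 1 symbol entered gene results. Entrez identifiers of 20351 were found in a RefSeq gene table of assembly GRCm38.p6, which was used for names alone and changed 0 symbols. No build is named in the sources used here, so no coordinates are given. Each of the 12393 genes was represented by the probe set with the highest mean of both group means, and 7094 genes with such a mean of at least 4 were kept. Folds are those of that probe set. Among the genes named or followed, 60 called ones had several kept probe sets, which lay over 2 log2 units apart in 17. A group mean under 4 was treated as near background, and a fold against it is given as a lower bound computed against a level of 4. The bounded median of a list was taken after values under 4 were set to 4. Near-identical genes such as Lyz1 and Lyz2, Hspa1a and its neighbour Hspa1b, and the class I and class II MHC genes can share probes, so their single values are uncertain. The viral E4ORF1 transcript is not a mouse gene and has no named probe set here.

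Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend). The spread came from the 3 fresh arrays alone, with 2 residual degrees of freedom and 1.43 from the prior, and the lone exEC array was assumed to vary like the fresh ones. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes kept. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The labels do not say whether the fresh pools came from separate mice or days, so p-values measure the spread between these samples, which may be technical in part, and no p-value includes the variation between exEC cultures. SE is the standard error of the log2 difference in that fit.

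In all, 30 gene lists were fixed before the data were examined, together with the groups, the tests, the thresholds, the alternatives and the rule for named genes. Their shift was tested with camera at a preset correlation between genes of 0.01, adjusted over the 29 lists with at least 2 genes kept. Camera with a correlation estimated from the arrays and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run beside it. The estimated correlation and the test that uses it rest on 2 residual degrees of freedom. Lists with an estimated correlation under the preset 0.01 lost their calls too, such as FOXO targets (-0.06), matrix genes (-0.04) and thymic niche factors (-0.02). A call lost in that test can come from its few degrees of freedom, and does not show that correlation between genes undid it. The rule named the 8 genes with the largest rise and the 8 with the largest fall measured in both groups, the 5 highest genes on either side that were near background in the other group, up to 4 called members of each list (or the 2 highest members where none was called), and 21 genes fixed in advance. Genes near background had to lie outside the fresh range, and symbols that are only clone identifiers were passed over. Any other gene named was chosen after its values were seen, and is marked so. Several genes stand in more than 1 list.

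Alternatives were no filter, a filter at 6, quantile normalization, centring each array on its median, no intensity trend, a robust fit, averaging a gene's probe sets, testing every probe set, leaving out each fresh array, calls by adjusted p alone or at 2 log2 units, limma's test against a minimum difference, and both other list tests. The script was tested on simulated data for the 7094 genes of this comparison, where it recovered 77.6% of genes changed by 1.2 log2 units, 89.6% of those changed by 2 and 97% of those changed by 4, with 4 false calls. The simulated list of 40 genes shifted by 2 was called, and 0 of 19 unchanged lists were. In the simulation genes varied independently, the lone array had the spread of the fresh ones, and far fewer genes changed than were called here. It checked the script, and does not show how many calls in the real data are false. Figures were drawn with matplotlib 3.10.9.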

Results

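Gene expression was compared between endothelial cells sorted fresh from the mouse thymus (3 arrays) and thymic endothelial cells that had been transduced with E4ORF1, an adenoviral gene that promotes survival, and expanded in culture (exEC, 1 array). The comparison asks how the expanded cells differ from freshly sorted ones. The fresh samples analysed are not known to be the cells that exEC came from. The fresh arrays resembled each other closely. Pearson's r across the 7094 genes kept was 0.990 to 0.992 and the median absolute difference was 0.12 to 0.14 log2 units between fresh arrays, against an r of 0.590 to 0.598 and a median difference of 0.95 to 0.96 between exEC and fresh arrays. Genes are not independent replicates, so these correlations describe the arrays and test nothing. The fresh RNA showed more 3′ bias, with a difference between the 3′ and 5′ control probe sets of beta-actin of 2.18 ± 0.15 log2 units (SD, n = 3) against 1.38 on the exEC array, and of 0.96 ± 0.10 against 0.52 for Gapdh.

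In exEC, cell cycle genes, Angpt2, Bmp4 and the BMP and activin antagonist Fst stood far above the fresh cells, and many capillary and arterial genes, Kitl, Cxcl12 and most immediate early genes stood far below them. The list calls behind this were lost with an estimated correlation, in a test that rests on 2 residual degrees of freedom (adjusted p = 0.353 for each). In all, 3325 of 7094 genes (46.9%) passed the test, 1893 higher and 1432 lower in exEC. Of the higher genes 353 were near background in the fresh cells, and of the lower genes 470 were near background in exEC. Without any estimate of spread, 1730 genes lay at least 1 log2 unit above the highest fresh array and 1335 as far below the lowest, while a lone array of 4 is the highest or lowest at any distance in 50% of genes by chance. The median log2 difference of the genes kept was 0.21, and the values given for single genes and lists are not corrected for that shift. Probe sets for control RNAs added at hybridization had a median difference of -2.1 (from -2.55 to -0.92), and lists were not scaled to them. Falls smaller than that could turn to rises under such a scaling. Among them are the medians of the pan-endothelial, venous, BMP, shear and matrix lists. Control RNAs spiked in before labelling differed by more, with a median of -4.89 (from -7.44 to -4.07). Of the lists called lower by camera, only the capillary (-8.58) and pericyte (-5.43) lists had a median larger in size than -4.89. When each fresh array in turn was set against the other fresh arrays in limma, 0 genes were called, with 476, 273 and 455 genes at an unadjusted p under 0.05, whereas exEC against the same pairs gave 3202, 3113 and 3101 calls.

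**Figure D1:**
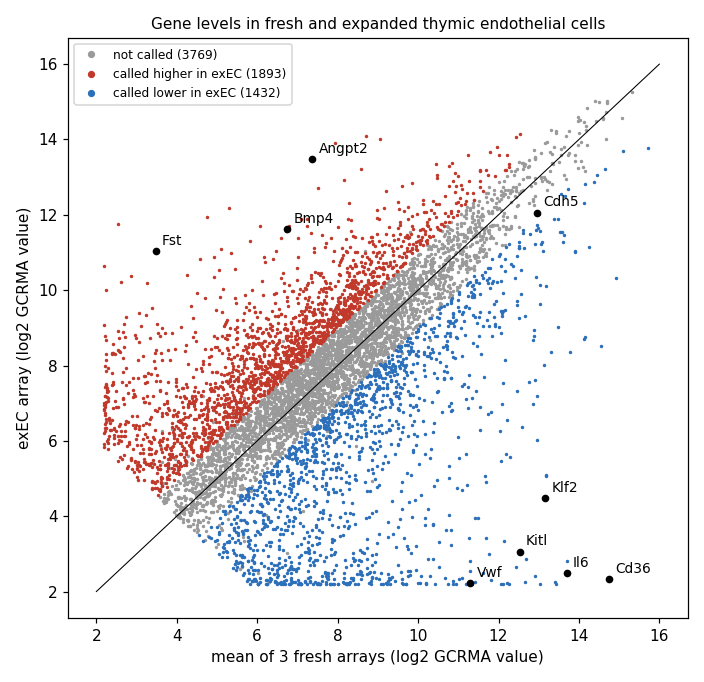
Each point is 1 of the 7094 genes kept, with the mean log2 GCRMA value of the 3 fresh arrays on the x axis and the log2 value of the exEC array on the y axis, and the line marks equal values. Genes called higher (1893, red) and lower (1432, blue) in exEC spread widely around the line, and Cd36, Il6, Vwf and Kitl lie near background in exEC.

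Among genes measured in both groups the largest rises were those of Adgrg3, an adhesion G protein-coupled receptor, and of genes of cell division. Adgrg3 rose from 4.76 ± 0.28 (SD, n = 3) to 11.93, a 144-fold difference (log2 difference 7.17, SE 0.262, adjusted p = 0.000408). Ube2c, Birc5, Ccnb2, Cdk1 and Ccna2, which act in mitosis or drive entry into it, were 62.7-fold to 120-fold higher. Angpt2, a ligand of the receptor Tek, rose by 6.11 log2 units to 13.48 (SE 0.062, adjusted p = 3.6e-05), and the monocyte chemokine Ccl2 rose by 5.97 to 13.9 (SE 0.313, adjusted p = 0.000766). Of the genes near background in fresh cells, the highest in exEC were Bex1 (at least 216-fold), Fst (at least 131-fold), Ankrd1 (at least 98.8-fold), the cytokinesis scaffold Anln (at least 82.7-fold) and the heparan sulfate sulfotransferase Hs6st2 (at least 74.7-fold).

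The largest falls measured in both groups were those of the flow-responsive transcription factor Klf2 (from 13.16 ± 0.08 to 4.48, 409-fold, SE 0.083, adjusted p = 3.19e-05) and of Zfp36, which promotes decay of AU-rich mRNAs (280-fold). Tcim (274-fold), Nrp1, a co-receptor for VEGF and semaphorins (123-fold), the scavenging chemokine receptor Ackr3 (111-fold), Vcam1 (107-fold), the phospholipid transfer protein Pltp (105-fold) and Rflnb (97.1-fold) followed. Other probe sets of Vcam1 and Pltp differed less, with -2.44 for the least changed of Vcam1 and -4.6 for Pltp. Those of Nrp1 fell at least as far as the 1 used, down to -8.45. Among genes near background in exEC, the highest in fresh cells were the fatty acid transporter Cd36 (14.74 ± 0.07, at least 1710-fold), the cytokine Il6 (13.7 ± 0.05, at least 833-fold), Sparcl1 (at least 832-fold), Rgcc (at least 690-fold) and Rgs5, a marker of pericytes (at least 675-fold).

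General endothelial genes remained expressed, and more of them fell than rose in the values as deposited. Their median and the falls of Cdh5, Pecam1 and Kdr were smaller in size than the shift of -2.1 of the hybridization controls. Of 32 members measured, 16 fell, 3 rose and 13 were not called, with a median difference of -0.95 (camera, adjusted p = 0.000573, and adjusted p = 0.433 with an estimated correlation). Of the 33 members on the array, 31 were at or above the background level in exEC and 32 in the fresh cells. Cdh5, which encodes the VE-cadherin used for sorting per the protocols, was at 12.95 ± 0.09 in fresh cells and 12.06 in exEC. Its difference of -0.88 missed the size threshold (SE 0.088, adjusted p = 0.00313) but passed it with arrays centred (-1.02). Pecam1 fell by 1.4 (SE 0.125, adjusted p = 0.00239), and the VEGF receptor Kdr fell by 1.02 (SE 0.198, adjusted p = 0.0166). The call of Kdr was lost without fresh replicate 2 (adjusted p = 0.078), without replicate 3 (-0.9) and without the filter (adjusted p = 0.0539). Tek fell by 4.11, Flt1 by 4.2 and Adgrl4 by 4.01, and Vwf, the platelet-binding factor stored in endothelial granules, went from 11.3 ± 0.17 to background (at least 157-fold). Eng rose by 1.03 (SE 0.125, adjusted p = 0.00508), and fell under the size threshold with arrays centred (0.9), with probe sets averaged (0.91), in another probe set (0.8) and without fresh replicate 1 (0.96). The other members called higher, chosen after their values were seen, were Emcn (1.38) and Myct1 (1.21).

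**Figure D2:**
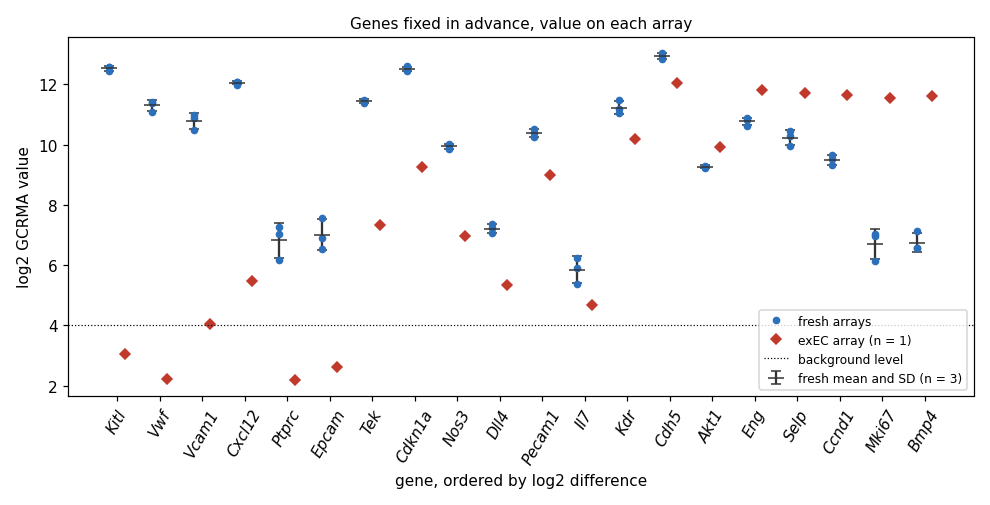
Log2 GCRMA values of 20 genes fixed in advance, ordered by their difference, with the 3 fresh arrays as circles, their mean and SD as bars and the exEC array as a diamond; the dotted line marks the background level of 4. Cdh5 stays near 12 in exEC while Kitl and Vwf lie under the line, and Bmp4 lies at 11.62 against a fresh mean of 6.75.

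Arterial and capillary genes mostly fell. Of 17 arterial genes 15 fell and 1 rose (median -3.29, or -2.9 with values under the background level set to it, here called the bounded median, adjusted p = 2.37e-06, and adjusted p = 0.353 with an estimated correlation), led by Mgp (at least 484-fold), the arterial transcription factor Sox17 (at least 217-fold), Nrp1 and Cxcl12. The Notch ligand Dll4 fell by 1.88 (SE 0.164, adjusted p = 0.00229), and the member that rose was Unc5b (1.17), named after its value was seen. Of 13 genes of capillaries and fatty acid handling 10 fell and 1, Kit, rose (1.75, named after its value was seen, a call lost without fresh replicate 3 with adjusted p = 0.0584). That list had a median of -8.58 and a bounded median of -6.86 (adjusted p = 5.84e-06, and adjusted p = 0.353 with an estimated correlation), and Cd36, Rgcc, Timp4 (at least 407-fold) and the lipase Lpl (at least 414-fold) fell furthest. Pericyte markers (median -5.43, bounded -3.73) were lower beside this list.

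Of 15 venous and leukocyte-recruiting genes, 10 fell and 2 rose (median -1.66, adjusted p = 0.000523, and adjusted p = 0.353 with an estimated correlation). The apelin receptor Aplnr (at least 528-fold), the L-selectin ligand Glycam1 (at least 299-fold), the thymocyte chemoattractant Ccl25 (at least 114-fold) and Vcam1 fell furthest. The members that rose were Selp, a selectin that binds circulating progenitors (1.5, SE 0.224, adjusted p = 0.00854, but 0.0532 without fresh replicate 1, and a difference of 0.92 in another probe set), and the venous transcription factor Nr2f2 (1.85, named after its value was seen, adjusted p = 0.0534 without fresh replicate 2). Thymic epithelial and fibroblast markers, whose cells can also make Ccl25 or Vcam1, were lower beside this list (medians -3.12 and -4.78, bounded -1.91 and -3.96). Lymphatic genes were not called as a list by camera (8 genes, 5 higher and 1 lower, median 2.4, bounded 2.31, adjusted p = 0.178) but were by fry (adjusted p = 0.0104). Pdpn rose by 3.87 and Sema3a and Reln rose from background (at least 6.1-fold and at least 4.8-fold), while Fgl2 fell (at least 7.1-fold). Tip cell genes went both ways, with 6 of 18 higher and 7 lower (median 0.23, mean 0.13, while camera's direction was down, adjusted p = 0.772, but 0.0277 by fry). Angpt2 and the vasodilator peptide Adm (36.9-fold) rose, whereas Igfbp3 (34.2-fold) and the Cxcl12 receptor Cxcr4 (at least 5.81-fold) fell.

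Bmp4, a ligand of BMP receptors with a reported role in the thymic epithelium, rose from 6.75 ± 0.33 (SD, n = 3) to 11.62, a 29.3-fold difference (log2 difference 4.87, SE 0.301, adjusted p = 0.00108, 1 probe set). The pathway list, which holds Bmp4, mostly fell, with 12 of 18 members lower and 3 higher (median -1.53, -0.94 without the filter, adjusted p = 0.00297, and adjusted p = 0.353 with an estimated correlation). Fst rose with Bmp4, and Id4 (at least 16.1-fold) and Bmp2 (at least 13.1-fold) fell. The other member called higher, Smad5 (1.15, named after its value was seen), lost its call without the filter (adjusted p = 0.0681), with probe sets averaged (0.65), in another probe set (0.15) and without any 1 fresh array. The BMP target genes Id1 (-1.31), Id2 (-1.43, and -0.89 in another probe set), Id3 (-1.22), Smad6 (-1.63) and Smad7 (-1.76) and the receptor gene Bmpr1a (at least 7.94-fold), all named after their values were seen, were called lower. The median of these target genes turned from -1.43 to 0.67 when the exEC array was shifted by its hybridization controls. The call of Id1 was lost without fresh replicate 1 (adjusted p = 0.0907) and without the filter (0.0628), and that of Smad7 without replicate 2 (0.0703), replicate 3 (0.082) or the filter (0.0532).

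The factors with reported roles in the thymic niche, Bmp4 among them, were mostly lower in exEC, with 13 of 19 lower and 3 higher (median -3.45, bounded -2.02, -1.32 without the filter, adjusted p = 0.000523, and adjusted p = 0.353 with an estimated correlation). Kitl, which supports early progenitors, went from 12.53 ± 0.08 to 3.06 (at least 369-fold, and -3.88 log2 units in the least changed of 4 probe sets), Cxcl12 fell by 6.58 (SE 0.065, adjusted p = 3.45e-05), and Il6 and Ccl25 fell to background. Il7 was at 5.84 ± 0.45 against 4.66 (difference -1.18, SE 0.403, adjusted p = 0.0685), and passed the threshold with arrays centred (adjusted p = 0.0393) and without fresh replicate 3 (adjusted p = 0.0405). Fgf7 was near background on the 4 arrays (2.21 to 2.26) and was not tested. The members called higher were Bmp4, Selp and Csf1 (2.31, named after its value was seen). Fibroblast and pericyte marker lists, whose cells also make some of these factors, were lower in exEC as well, with medians of -4.78 and -5.43 (bounded -3.96 and -3.73).

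**Figure D3:**
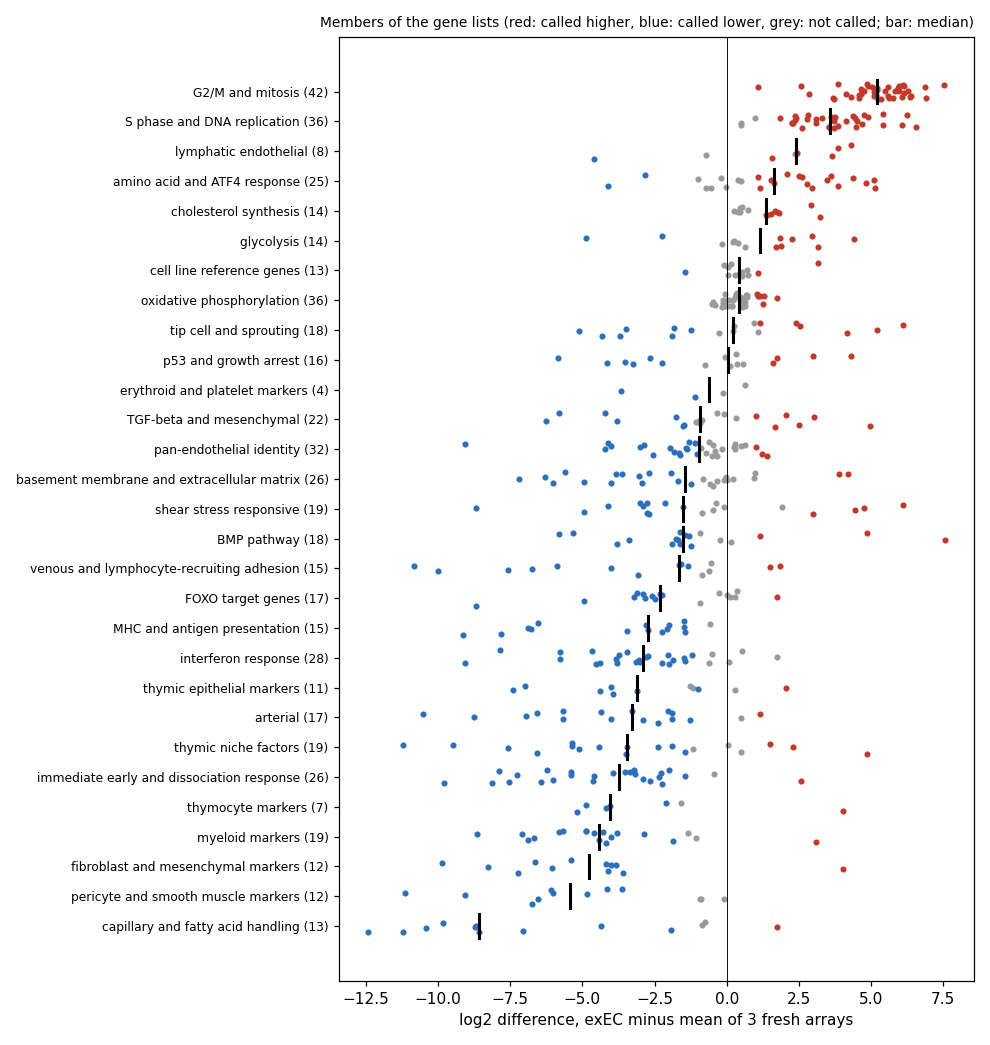
Log2 difference between exEC and the mean of the 3 fresh arrays (x axis) for each measured member of the 29 gene lists tested (y axis, number of members in brackets), with called members in red or blue, uncalled ones in grey and the median as a bar. The G2/M list has its median at 5.21 and the capillary list at -8.58.

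Proliferation genes rose nearly without exception. All 42 measured genes of G2 phase and mitosis were called higher (median 5.21, bounded 4.56, adjusted p = 9e-12, and adjusted p = 0.353 with an estimated correlation), among them Anln, Ube2c, Kif20a (at least 33.6-fold) and Cenpf (at least 34-fold). Mki67, a marker of cycling cells, rose from 6.71 ± 0.50 to 11.56 (28.9-fold, SE 0.445, adjusted p = 0.00255). Of 36 S phase genes 33 rose and 0 fell (median 3.58, bounded 3.04, adjusted p = 2.62e-09, and adjusted p = 0.353 with an estimated correlation), with Tk1 (at least 39.4-fold), Pole (at least 29.7-fold), Mcm5 (at least 27.2-fold) and Hells (43-fold) at the top. The cyclin Ccnd1 rose by 2.16 (SE 0.16, adjusted p = 0.00157), and the cell cycle inhibitor Cdkn1a fell by 3.26 (SE 0.083, adjusted p = 0.000224). Akt1 was 0.66 higher, under the size threshold (SE 0.067, adjusted p = 0.00329). Genes of the p53 response and growth arrest went both ways, 4 of 16 higher and 6 lower (median 0.03, mean -0.65, camera's direction down, adjusted p = 0.314, but 0.0027 by fry). The median was under 0 in 5 alternatives (-0.103 to -0.0147). Aen rose 19.7-fold, Btg2 fell 11.6-fold, and Fas (at least 41.5-fold) and Perp (at least 8.26-fold) fell to background.

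Genes of biosynthesis rose in part, while those of oxidative phosphorylation were called higher less often than all genes kept (1893 of 7094). Of 14 cholesterol synthesis genes 8 rose and 0 fell (median 1.37, adjusted p = 0.00763, and adjusted p = 0.366 with an estimated correlation), including Sqle (9.4-fold), Fdps (7.6-fold), Cyp51 (3.49-fold) and the regulator Srebf2 (at least 2.85-fold, but 0.99 log2 units and not called with probe sets averaged). Of 25 genes of the amino acid and ATF4 response 16 rose and 2 fell (median 1.63, adjusted p = 0.0322, and adjusted p = 0.353 with an estimated correlation, and 0.144 with the filter at 6). The serine pathway enzymes Psat1 (35-fold, a call lost without fresh replicate 2 with adjusted p = 0.0685), Phgdh (28-fold), Mthfd2 (at least 18.9-fold) and Shmt2 (20.5-fold) led it, though another Shmt2 probe set differed by 0.24 only. Glycolysis genes were not called as a list by camera (7 of 14 higher, 2 lower, median 1.16, adjusted p = 0.072, but 0.00022 by fry, and a median of 0.39 with adjusted p = 0.0445 without the filter). Hk2 (at least 13.7-fold), Pgk1 (9.01-fold) and Pkm (7.81-fold) rose, and the regulator Pfkfb3 fell 29.7-fold. For oxidative phosphorylation 6 of 36 genes rose and 0 fell (median 0.41, adjusted p = 0.0669, but 0.01 by fry, 0.0151 without the filter and 0.0479 without fresh replicate 1), led by Atp5b (3.34-fold), Cyc1 (2.46-fold), Ndufs1 (2.37-fold) and Uqcrc1 (2.23-fold).

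Genes that respond to flow and to FOXO factors were mostly lower, and both lists hold Klf2 and Klf4. Of 19 shear-responsive genes 10 fell and 4 rose (median -1.51, adjusted p = 0.00766, and adjusted p = 0.366 with an estimated correlation). Klf4 fell 30.8-fold and the nitric oxide synthase Nos3 by 2.99 (SE 0.087, adjusted p = 0.000277), while Angpt2, the quinone reductase Nqo1 (26.8-fold) and the vasoconstrictor Edn1 (21.7-fold, named after its value was seen) rose. Of 17 FOXO targets 10 fell and 1 rose (median -2.3, bounded -1.85, adjusted p = 0.00203, and adjusted p = 0.353 with an estimated correlation), among them Ccng2 (8.59-fold) and Tnfsf10 (at least 3.61-fold). Immediate early genes, which are known to respond to tissue dissociation, were high in the fresh cells. Of 26 measured, 24 fell in exEC and 1 rose (median -3.74, adjusted p = 2.32e-10, and adjusted p = 0.353 with an estimated correlation). Hspa1a (at least 344-fold), Zfp36, Nr4a1 (at least 179-fold) and Fosb (at least 78.6-fold) were among those that fell, and Fosl1 rose by 2.57 (named after its value was seen).

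Interferon and antigen presentation genes were lower in exEC. Of 28 interferon response genes 23 fell and 0 rose (median -2.89, bounded -2.59, adjusted p = 2.56e-08, and adjusted p = 0.353 with an estimated correlation), with the chemokines Cxcl9 (at least 153-fold) and Cxcl10 (at least 155-fold), the transcription factor Irf1 (54.9-fold) and the GTPase Iigp1 (54.4-fold) at the top. Of 15 MHC and antigen presentation genes 14 fell and 0 rose (median -2.72, adjusted p = 6.98e-06, and adjusted p = 0.366 with an estimated correlation). The class II genes H2-Aa (at least 162-fold), H2-Ab1 (at least 66.2-fold) and H2-Eb1 (at least 37.9-fold) and the protease Ctss (at least 33.6-fold) went to background. Myeloid markers, whose cells carry class II and Ctss, fell beside them, with a median of -4.41 (bounded -2.84).

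Matrix genes were lower on balance. Of 26 basement membrane and matrix genes 14 fell and 2 rose (median -1.44, adjusted p = 0.000848, and adjusted p = 0.353 with an estimated correlation, and a median of -0.40 with adjusted p = 0.07 with the filter at 6). Bgn (at least 113-fold), Col6a2 (at least 22.7-fold), Col6a1 (at least 22.5-fold) and Col15a1 (at least 21.2-fold) were among those that fell, and Col18a1 (18.3-fold) and the protease inhibitor Timp1 (14.9-fold), named after their values were seen, rose. TGF-beta and mesenchymal genes were not called as a list by camera (6 of 22 higher, 8 lower, median -0.92, adjusted p = 0.0571, but 0.00462 by fry, 0.0151 without the filter, 0.0448 without fresh replicate 1 and 0.0466 without replicate 3). Myl9 (at least 43.6-fold), Tgfbi (at least 22.8-fold) and the TGF-beta target Pmepa1 (at least 9.76-fold) fell, and fibronectin, Fn1, rose by 4.96 to 14.02. Fibroblast markers (median -4.78, bounded -3.96) and pericyte markers (median -5.43, bounded -3.73) were lower beside these lists.

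Marker genes of other thymic cells were present in the fresh sorts and mostly near background in exEC. Of 61 pericyte, fibroblast, myeloid and epithelial markers at or above 4 on each fresh array, 15 were so in exEC too. Among these, Acta2 (10.21 in fresh cells, 10.11 in exEC), Tagln (9.24 and 8.31) and Mylk (10.11 and 9.21) stayed high and were not called. Of 12 pericyte and smooth muscle markers 9 fell and 0 rose (median -5.43, bounded -3.73, adjusted p = 1.03e-05, and adjusted p = 0.353 with an estimated correlation), with Rgs5 at 13.4 ± 0.06 and Pdgfrb at 11.27 ± 0.21 in fresh cells (at least 154-fold), then Kcnj8 (at least 61.4-fold) and Rgs4 (at least 27.3-fold). Of 12 fibroblast markers 11 fell and 1 rose (median -4.78, bounded -3.96, adjusted p = 8.89e-05, and adjusted p = 0.366 with an estimated correlation), with Col3a1 at 12.06 ± 0.13 (at least 266-fold), Dcn (at least 206-fold), Col1a2 (at least 92.1-fold) and Lum (at least 28.7-fold). The marker that rose was Thy1 (16.4-fold), which the thymocyte list also holds. Of 19 myeloid markers 16 fell and 1, Cd14, rose (8.48-fold), with a median of -4.41 (bounded -2.84, adjusted p = 0.00012, and adjusted p = 0.465 with an estimated correlation, and a median of -1.06 with adjusted p = 0.543 with the filter at 6). Lyz1 was at 10.86 ± 0.85 in fresh cells (at least 116-fold), followed by Lyz2 (at least 39.4-fold), Ctss and C1qb (at least 32.4-fold), and Ptprc, which encodes the CD45 used for depletion, was at 6.82 ± 0.58 against 2.2 (at least 7.06-fold). Acta2, Tagln, Mylk, Thy1 and Cd14 were named after their values were seen.

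Of 11 thymic epithelial markers 7 fell and 1 rose (median -3.12, bounded -1.91, adjusted p = 0.0197, and adjusted p = 0.524 with an estimated correlation, 0.054 by fry, and a median of -1.14 with adjusted p = 0.225 with the filter at 6). Krt8 (at least 62.3-fold), Dsp (at least 38.1-fold) and Krt18 (16-fold) fell. Of the 20 epithelial markers on the array, 15 were at least 4 on each fresh array and 6 were at least 4 in exEC. Epcam, whose protein was gated out per the protocols, went from 7.01 ± 0.51 to 2.63 (at least 8.03-fold). Of 7 thymocyte markers 5 fell and 1 rose, which was not called as a list by camera (median -4.04, bounded -2.25, adjusted p = 0.0563, but 0.0279 by fry, 0.0244 without fresh replicate 2 and 0.0466 without replicate 3). It was called lower without the filter at a median of -1.19 (adjusted p = 0.0126), and turned to 1.22 with the filter at 6 (adjusted p = 0.82). Satb1 (at least 10.8-fold), Rag1 (at least 8.49-fold), Cd247 (at least 7.07-fold) and Cd3d (at least 4.76-fold, adjusted p = 0.0634 without fresh replicate 3) fell. Of the B cell markers 1 gene was kept, Ighm, which fell (at least 3.74-fold, adjusted p = 0.0526 without fresh replicate 1). Among 4 erythroid and platelet markers 2 fell, Pf4 (at least 5.78-fold) and Hbb-b2 (2.14-fold, but a difference of -0.55 with probe sets averaged), without a list call by camera (median -0.61, adjusted p = 0.201, but 0.0086 by fry). Reference genes were not called as a list by camera (13 genes, 2 higher and 1 lower, median 0.44, adjusted p = 0.176, but 0.0013 by fry). Among them Pgk1 rose 9.01-fold, Sdha rose by 1.08 in 1 probe set and differed by -0.29 in another (0.95 with arrays centred and 0.4 with probe sets averaged, not called), and B2m fell by 1.44.

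Camera called 20 of 29 lists, 16 lower and 4 higher, and 0 with an estimated correlation (smallest adjusted p = 0.35, with 1 list at an unadjusted p under 0.05), while fry gave 28 of 29 lists. Adjusted over the list alone, the number of called members was the same in each list as over all genes tested.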

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

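All tests in this part were chosen after the results they bear on were seen.

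The control probe sets on the arrays, which no comparison used, differed between exEC and the fresh arrays. The 18 probe sets for RNAs added at hybridization had a median log2 difference of -2.1, and the 24 for RNAs spiked in before labelling one of -4.89. A further set left out, probe sets with no single gene symbol, gave 196 of 899 at least 1 log2 unit above the highest fresh array.

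Pattern 1 is the difference in control probe sets. Bias by probe position as a cause of called genes stays open, since the 3′ to 5′ difference of beta-actin changed by 0.80, less than the median absolute difference of 1.97 of called genes, and its size for other genes is not known. A different amount of control RNA, of labelled target or of its scaling on the exEC array cannot be told apart, as the hybridization controls shifted by -2.1 (from -2.55 to -0.92) and the design holds 1 exEC array. No biological explanation was tested.

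Pattern 2 is the fall of pericyte, fibroblast, myeloid and epithelial markers. Reduced sensitivity of the exEC array is argued against, because the 54 markers had a median difference of -4.23 while lists matched on fresh level lay between -0.33 and 0.42, and with values under the background level set to it their median was -3.03 against the same matched range. Other cells in the fresh sorts are a candidate explanation. Of the markers on the array 76.2% (61 of 80) were at least 4 on each fresh array, against 54.7% of all genes (one-sided exact binomial p = 5.36e-05). That p-value takes the markers as independent, but they vary together (estimated correlation 0.82 for myeloid and 0.86 for epithelial markers), so it overstates the evidence. Rgs5 was at 13.4, Col3a1 at 12.06 and Lyz1 at 10.86. By the protocols, a VE-cadherin gate should have left out pericytes and fibroblasts, and CD45 and EpCAM gates myeloid and epithelial cells. The description of the fresh samples instead names stromal cells without CD45, and the labels do not settle which sort was used. Loss by the endothelial cells themselves stays open, as 15 of the 61 markers that were at least 4 on each fresh array were also at least 4 in exEC. No pure fresh sample separates the explanations. Whether the share of other cells differed between the fresh sorts was not decided. In 4 of 4 marker lists the range exceeded that of matched lists (myeloid range 1.16, matched 95th percentile 0.18), but so did the pan-endothelial range (0.15 against 0.10). That endothelial range does not count against a differing share. On fresh array 1 pan-endothelial genes lay lowest (-0.06) and myeloid (0.65), epithelial (0.51) and fibroblast (0.26) markers highest, while pericyte markers lay highest on array 2 (0.14).

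Pattern 3 is the rise of Bmp4 beside the fall of Id1, Id2, Id3, Smad6 and Smad7. Scaling is argued against for Bmp4, which differed by 4.74 and 4.84 under both other scalings and by 6.97 after a shift of the exEC array by its hybridization controls. For the 5 genes it stays open, as their median was -1.56 and -1.5 under both scalings but 0.67 after that shift. Dilution of endothelial RNA in the fresh sorts is argued against for Bmp4, since it lay at least 5.75 above the pan-endothelial median without any 1 fresh array, where members of that list had an SD of 2.05. A response of the fresh cells to isolation may have raised the 5 genes, and stays open because their median lay 2.31 from that of the immediate early list, which does not exclude a smaller response. Transduction, culture and the medium differ together between the groups, and none was tested.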

How the results depend on the processing

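Alternatives fixed beforehand changed which genes passed. Among genes called in both, 0 turned direction between the values as deposited and any other filter, scaling, trend, probe choice or left-out fresh array. That count tests little, since a turn would need a move from at least 1 log2 unit above 0 to as far below it, or the reverse. A filter or trend leaves the difference unchanged, and centring moves all genes alike. Calls ran from 2266 to 3465 over these alternatives, with 53% of called genes higher after quantile normalization and 51.9% after centring, against 56.9%. Of 169 genes followed under these alternatives 19 changed call or direction somewhere. Not each gene was present under each alternative, with 124 left under the filter at 6 and some missing with probe sets averaged. Causes were not tested, except where fewer genes or arrays entered. The lone exEC array and the pile-up of values near background limit every result, and no alternative addresses the former or scaled the arrays to control probe sets. No paired analysis was possible, because only 1 exEC array was analysed.

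By adjusted p alone 5099 genes passed, 2987 higher. Every probe set on its own gave 5209, 3027 higher and 2182 lower. At 2 log2 units 1636 passed, 809 higher and 827 lower, and limma's test against a minimum difference gave 1209 higher. At a distance of 2 units 719 genes lay above and 775 below the fresh range. With the filter at 6, 920 genes were called lower, 838 lay below the range and r between exEC and fresh arrays was 0.526. Without a filter that r was 0.858, and between fresh arrays 0.995. After quantile normalization it was 0.596.

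With an estimated correlation the 20 called lists lost their calls at unchanged medians, with adjusted p from 0.353 to 0.524: ATF4 1.63, arterial -3.29, matrix -1.44, BMP -1.53, capillary -8.58, cholesterol 1.37, fibroblast -4.78, FOXO -2.3, G2/M 5.21, immediate early -3.74, interferon -2.89, MHC -2.72, myeloid -4.41, pan-endothelial -0.95, pericyte -5.43, S phase 3.58, niche -3.45, shear -1.51, epithelial -3.12 and venous -1.66. By fry, reference genes (0.44), erythroid (-0.61), glycolysis (1.16), lymphatic (2.4), oxidative phosphorylation (0.41), p53 (0.027), TGF-beta (-0.92), thymocyte (-4.04) and tip cell (0.23) lists passed, and epithelial markers (-3.12) did not (adjusted p = 0.054).

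With the filter at 6 the calls of ATF4 (1.34), matrix (-0.40), myeloid (-1.06) and epithelial (-1.14) lists ended, and thymocyte markers turned to 1.22. The p53 list turned to -0.0587 with the filter at 6, -0.0598 without one, -0.103 centred and -0.0912 after quantile normalization. Without a filter glycolysis (0.39), oxidative phosphorylation (0.41), TGF-beta (-0.93) and thymocyte (-1.19) lists were called. Leaving out 1 fresh array gave -0.0147 to 0.0528 for p53, 0.37 to 0.43 for oxidative phosphorylation, -0.96 to -0.88 for TGF-beta and -4.26 to -3.70 for thymocyte markers. It gave -0.155 to 0.00686 for Acta2, a gene not called and named after its value was seen.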

Other observations

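Gene families read from gene symbols were chosen after the data were seen, as were their tests. Of 15 families 10 were called by camera and 0 with an estimated correlation, and the 10 kept the direction of their median under both scalings and without each fresh array. Aminoacyl-tRNA synthetases rose, 13 of 15 higher and 0 lower (median 1.89, bounded 1.81, adjusted p = 0.00203, and adjusted p = 0.346 with an estimated correlation), with Rars at 12.1-fold and Cars at least 4.95-fold higher. Mitochondrial ribosomal proteins rose in 47 of 74 genes and fell in 0 (median 1.15, adjusted p = 8.33e-06, and adjusted p = 0.346 with an estimated correlation), whereas cytosolic ribosomal proteins had 6 of 45 higher and 2 lower (median 0.49, adjusted p = 0.00283, and adjusted p = 0.346 with an estimated correlation). Nucleoporins (12 of 15 higher, median 1.54), subunits of the CCT chaperonin (6 of 7, median 1.58) and proteasome subunits and assembly factors (17 of 37, with 3 lower, median 0.89) rose as families, with adjusted p of 0.00129, 0.00751 and 0.00129, each with an adjusted p = 0.346 with an estimated correlation.

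Chemokines fell in 11 of 15 genes and rose in 2 (median -4.17, or -2.84 with values under the background level set to it, adjusted p = 0.00129, and adjusted p = 0.346 with an estimated correlation). Cxcl9 (at least 153-fold) and the neutrophil chemokine Cxcl1 (92.9-fold) were lower, while Ccl2 and its neighbour Ccl7 (12.3-fold, a call lost without fresh replicate 2 or 3 with adjusted p of 0.0664 and 0.0616) were higher. Myeloid and fibroblast markers, whose cells make some of these chemokines, fell as well (medians -4.41 and -4.78, bounded -2.84 and -3.96). Kruppel-like factors fell in 8 of 9 genes (median -2.33, adjusted p = 0.0026, and adjusted p = 0.346 with an estimated correlation), Klf9 by 17-fold, and Klf16 was the 1 called higher, a call lost without fresh replicate 2 (adjusted p = 0.0605). Regulators of G protein signalling (5 of 7 lower, median -2.61, bounded -2, adjusted p = 0.0436, and adjusted p = 0.463 with an estimated correlation) and cytochromes P450 (5 of 9 lower and 1 higher, adjusted p = 0.0224, and adjusted p = 0.346 with an estimated correlation) fell. Rgs5 and Rgs4 are also pericyte markers, and that list fell as well (median -5.43, bounded -3.73). Hox genes, which are tied to body position, were not called as a family (3 of 8 higher, 3 lower, adjusted p = 0.93), but Hoxd10 rose from background (at least 8.21-fold) and Hoxd9 rose 6.6-fold while Hoxa5 fell 6.79-fold. Semaphorins and plexins (4 of 8 higher, 1 lower, adjusted p = 0.739), integrins (1 of 6 higher, 2 lower, adjusted p = 0.641), ADAM proteases (2 of 9 higher, 4 lower, adjusted p = 0.106) and solute carriers (25 of 111 higher, 25 lower, adjusted p = 0.93) were not called as families. Within them Sema3e rose from background (at least 25.9-fold), Itga3 rose 12.9-fold and Itgb5 fell to background (at least 29-fold).

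For 2 hypotheses raised by single genes, the list and the test were written before the values of the other members were seen. The rise of Ankrd1 and Ccn2 raised the hypothesis that targets of the transcriptional co-activator YAP are higher as a set, and 8 measured members whose values were already known were set aside, 5 of them called higher and 1 lower. The 10 remaining members had a median of -0.12, with 3 called higher and 2 lower, where matched lists lay between -0.92 and 1.26 around 0.19. The rise of Adm, Angpt2, Slc2a1, Pgk1 and Hk2 raised that of a hypoxia response, and these and Apln, 6 measured members and all called higher, were set aside as already known. The 18 remaining members had a median of -0.41, with 4 higher and 8 lower, against -0.57 to 0.98 around 0.2. Neither list stood above matched lists. Both medians lay under the matched median, the value set beforehand as counting against each hypothesis. By that rule both results count against the hypotheses. Both medians lay within the range of the matched lists and members went both ways, so this evidence is weak and excludes neither hypothesis.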
